A study of Caenorhabditis elegans with 15 samples.

How the data were processed

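Total RNA of synchronized C. elegans L1 larvae was labelled with biotin and hybridised to 15 Affymetrix arrays, per the labels' protocols. The deposited table holds log2 signals, 1 value per probe set and array. Affymetrix Power Tools 1.14 made them, per the submitters' processing notes, while the background correction, normalization and summary method are not given in the sources used here. The scale was taken as log2 from the range of the deposited values, whose array minima were between 2.75 and 2.99 and maxima between 14.5 and 15.0. Detection calls were not used here. If the authors' normalization gave the arrays a common distribution, a change in total RNA per larva would not show in the values, and differences are therefore relative to the other genes on the array.

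Each array was placed in its group by its labels, and 0 value columns were left without a sample. Probe sets were named from the platform annotation supplied with the values. Of 22625 probe sets 77 were controls, 20766 had 1 gene, 887 had several and 895 had none; probe sets with several genes or none entered no gene-level test. Of the 20766 probe sets, 20701 had a gene identifier found in a RefSeq table of assembly WBcel235, which changed 0 symbols. Coordinates are not printed because the files name no genome build, and that table served for names and gene neighbours. A gene was represented by its probe set with the highest mean over the 15 arrays, which gave 17118 genes, 2981 of them with more than 1 probe set and 4267 represented by a probe set with an x or s suffix, which can bind related transcripts.

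Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit with 1 mean per group over all 15 arrays, then eBayes), so that the 5 groups of 3 arrays shared 1 estimate of spread for each gene. P-values were two-sided and Benjamini-Hochberg adjusted over the 17118 genes, with a threshold of 0.05, and counts of larger changes used a log2 difference of 1. The comparisons were UV against mock treatment in N2 and in xpa-1, starvation against mock treatment in N2, UV against starvation in N2, mock-treated xpa-1 against mock-treated N2, and the difference of the UV responses (interaction). The comparisons, the tests, the gene lists, the rule for named genes and the alternatives, except for 1 named later, were chosen before the data were examined.

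For gene groups, 47 lists of DNA repair, stress, metabolism, growth, cuticle, immune, neuropeptide and tissue marker genes were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 47 lists in a comparison, and again with the correlation estimated from the data. Counts of members were given at adjusted p under 0.05 over all genes and adjusted over the list alone. Lists whose call held with an estimated correlation numbered 3 of 23 in the N2 UV response, 5 of 13 in the xpa-1 UV response, 11 of 21 in starvation, 2 of 4 between the mock-treated strains, 0 of 13 in the interaction and 8 of 21 between UV and starvation. The text names, for each comparison, genes from the 10 largest and 10 lowest differences among called genes whose groups do not overlap (for the interaction, among called genes), from the up to 4 called members of each list with the largest differences, and from xpa-1, daf-16, egl-27, daf-2, sod-3, egl-1, ced-13 and cep-1 whatever their values, with some left out for length. Genes of the pals family other than pals-6 were counted as a family chosen after their values were seen.

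Agreement between comparisons was given as correlations across genes and as overlaps of called genes beside the number that independent lists would share. For the pair of comparisons that uses the mock-treated N2 arrays on both sides, 100 simulations of unchanged groups were run. Alternatives were another quantile normalization, centring of arrays on their medians, leaving out genes with a mean below the 25th percentile, the mean of a gene's probe sets, a test of every probe set, the compared groups alone in the fit, the replicate number as a block, eBayes with trend and robust options, array weights, limma's treat against a log2 difference of 0.5, and leaving out each array in turn. For lists, fry was run beside camera. Genes represented by probe sets without an x or s suffix were tested as an alternative chosen after seeing the data.

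The fits were tested on simulated data in which 200 of the 17118 genes were shifted. For the N2 UV comparison 82.1% of genes shifted by 0.5 were called, for the xpa-1 UV comparison 88.1%, for starvation 86.6%, for the mock-treated strains 85.1%, for the interaction 32.8% and for UV against starvation 94.0%, and 100% of those shifted by 1 or 2 in each comparison. Unshifted genes called numbered 6 to 18 in a comparison. The real comparisons called 5.7% to 52.9% of genes, a larger share than was shifted here. The adjusted threshold depends on that share, so the rates for shifts of 0.5 need not hold in the real fits. For lists, tested in the N2 UV comparison, camera found 20 of 20 lists shifted by 0.5 and called 0 of 940 unshifted ones. The simulated genes varied independently of each other. These list figures therefore do not show how often correlated genes would give a false call in the real data. The median residual SD of a gene was 0.121 on the log2 scale. Figures were drawn with matplotlib 3.10.9.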

Results

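Transcript levels were measured on 15 Affymetrix C. elegans arrays carrying total RNA of synchronized L1 larvae, the first larval stage. The larvae were wild type (the N2 strain) or mutant for xpa-1, the worm counterpart of the human XPA gene, whose product verifies damage in nucleotide excision repair of UV lesions. Mock-treated and UV-treated larvae of each strain made up 4 groups and starved N2 larvae the fifth, with n = 3 arrays in each. Larvae spent 4 h on food before UV and were harvested 6 h after it. N2 received 60 mJ/cm2 and xpa-1 received 10 mJ/cm2, so strain and dose changed together wherever the UV responses of the strains were compared. How long the starved larvae went without food is not given in the sources used here. The study's title names the transcription factors DAF-16 (FoxO) and EGL-27 (GATA family) in the response to DNA damage, and their genes were therefore examined in each comparison.

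Across the 22548 probe sets that are not controls, array medians lay between 6.20 and 6.27 on the log2 scale. Correlations between arrays of 1 group ran from 0.9948 to 0.9985, across the 17118 genes, which are not independent replicates. Starved arrays correlated with the other groups at 0.902 to 0.9204. The first principal component carried 74.3% of the variance and separated the starved larvae from the others, and the second, with 11.2%, separated UV-treated from mock-treated larvae of both strains. In this design the number of arrays limits the precision, and p-values measure the spread between these samples, since the labels do not say whether replicates came from separate cultures. Differences below are log2 differences ± SE from limma, and group levels are mean ± SD of the log2 signal. No detection calls were used, so a fold or log2 difference is a lower limit in size where the dimmer group lay at or below the 25th percentile of the arrays (4.48 to 4.62), as for pgp-8 in N2, ZK1025.3, dbd-2, C23G10.11, cest-5.2, srw-85 and, in xpa-1 larvae, ins-37.

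The gene mutated in the repair-deficient strain, xpa-1 (K07G5.2), was at 6.56 ± 0.01 in mock-treated N2, 6.48 ± 0.14 in UV-treated N2 and 6.29 ± 0.03 in starved N2, against 4.23 ± 0.21 in mock-treated and 4.44 ± 0.46 in UV-treated xpa-1 larvae (n = 3 each). The signal was thus lower in the mock-treated mutant than in mock-treated N2 (-2.33 ± 0.16, adjusted p = 9.94e-09), below the 25th percentile of every array (4.48 to 4.62). The mutant's level was not shown to lie above background, so this difference is a lower limit in size. Whether its probe set lies in the part removed by the mutation is not given, so the low signal is recorded as a measurement. In the UV response of xpa-1 larvae the gene was not called (0.22 ± 0.16, adjusted p = 0.372), and without replicate 3 of the UV-treated xpa-1 arrays the difference was 0.46 with an adjusted p of 0.0092.

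**Figure D1:**
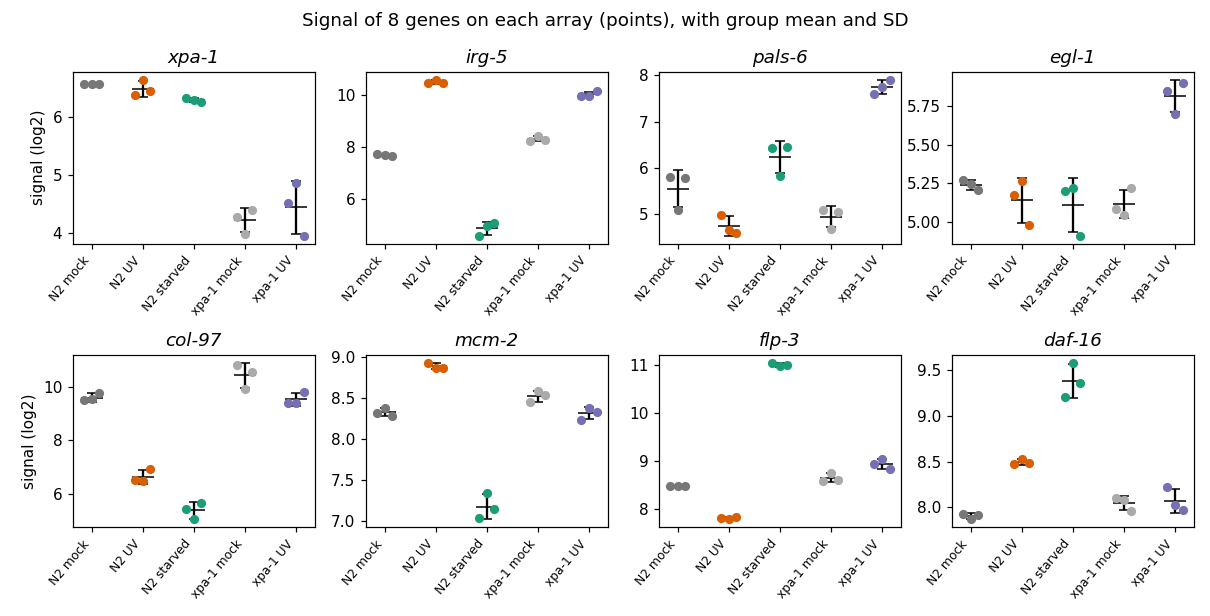
Log2 signal of 8 genes (vertical axes) in each of the 5 groups (horizontal axes); points are arrays, horizontal marks are group means and bars are SD (n = 3). The xpa-1 signal was low in both xpa-1 groups, irg-5 was high after UV in both strains, pals-6 and egl-1 were high in UV-treated xpa-1 larvae, and flp-3 and daf-16 were highest in starved N2 larvae.

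The UV response of N2 answered what the higher dose changed in repair-proficient larvae. UV raised irg-5, an infection response gene, 7.06-fold, from 7.70 ± 0.04 in mock-treated to 10.52 ± 0.08 in UV-treated larvae (2.82 ± 0.10, adjusted p = 2.44e-12). The lipase-related gene lips-11 rose 6.96-fold and dod-22 rose 6.04-fold. The glutathione S-transferase gene gst-24 rose 5.67-fold and the ABC transporter gene pgp-8 rose 5.20-fold (SE of the log2 differences 0.09 to 0.12 from lips-11 to pgp-8). The collagen gene col-97 was 7.76-fold lower (-2.96 ± 0.20), the patched-related gene ptr-16 was 7.68-fold lower (-2.94 ± 0.11), abu-14 was 8.90-fold lower (-3.15 ± 0.12) and R12E2.15 was 12.5-fold lower (-3.65 ± 0.17, on a probe set that can bind related transcripts).

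Of 145 measured cuticle collagen genes, 71 fell and 10 rose after UV in N2, or 82 and 11 adjusted over the list alone (camera adjusted p = 1.41e-19, and adjusted p = 0.0233 with an estimated correlation). Examples were col-48 (-2.52 ± 0.14), col-104 (-2.18 ± 0.19) and col-107 (-2.07 ± 0.13). Among 80 hedgehog-related and patched-related genes, 34 fell and 7 rose, or 37 and 8 adjusted over the list alone (camera adjusted p = 7.05e-11, and adjusted p = 0.0233 with an estimated correlation). Besides ptr-16, the lowest were grl-5 at -2.45 ± 0.12, grd-5 at -2.43 ± 0.12 and ptr-6 at -2.40 ± 0.10. Molting genes went both ways, 15 of 30 lower and 4 higher, or 16 and 7 adjusted over the list alone. Their camera call in the lower direction (adjusted p = 5.13e-05) had an adjusted p = 0.0982 with an estimated correlation. The molting regulator gene mlt-10 fell by 1.71 ± 0.09 and the fibrillin-like gene fbn-1 rose by 1.53 ± 0.13.

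DNA replication genes rose by small amounts. Of 33, 23 were higher after UV in N2 by limma (28 adjusted over the list alone, median log2 difference 0.38), and camera gave adjusted p = 1.55e-11, with adjusted p = 0.0693 with an estimated correlation. The replicative helicase genes mcm-2 (0.56 ± 0.08), mcm-3 (0.55 ± 0.09) and mcm-6 (0.56 ± 0.07) and the origin recognition gene orc-1 (0.62 ± 0.11) were among them. In a list of 36 other DNA damage response genes 14 rose, or 17 adjusted over the list alone (camera adjusted p = 6.66e-05, and adjusted p = 0.107 with an estimated correlation). They were led by atl-1, the worm ATR kinase gene (0.70 ± 0.09), and pcn-1, which encodes the PCNA sliding clamp (0.54 ± 0.08). Of 14 nucleotide excision repair genes 3 rose, also adjusted over the list alone; xpb-1, a helicase gene of TFIIH, was one of them (0.45 ± 0.10). That list's camera call (adjusted p = 0.0218) had an adjusted p = 0.13 with an estimated correlation and ended without replicate 2 of the mock-treated N2 arrays (adjusted p = 0.0585). Ribosome biogenesis genes also rose, 15 of 29, or 21 adjusted over the list alone (camera adjusted p = 2.01e-07, and adjusted p = 0.0982 with an estimated correlation).

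A list of 6 genes, the p53 gene cep-1 and core cell death genes, did not pass camera's test in N2 (adjusted p = 0.998). The cell death activator gene egl-1 stood at -0.10 ± 0.10 (adjusted p = 0.613), ced-13 at 0.06 ± 0.09 and cep-1 at 0.09 ± 0.08. The FoxO gene daf-16 rose by 0.59 ± 0.09 on its brightest probe set (adjusted p = 9.51e-05). Tested over all probe sets, 2 of its 4 were called (0.59 each) and the others were not (0.22 with adjusted p = 0.22, and 0.29 with adjusted p = 0.0888). The GATA gene egl-27 at 0.10 ± 0.09 (adjusted p = 0.544) and the insulin receptor gene daf-2 at 0.06 ± 0.09 did not pass the test. The superoxide dismutase gene sod-3, a DAF-16 target, rose by 0.31 ± 0.10 (adjusted p = 0.039), a call that was lost without replicate 1 or 3 of the mock-treated (adjusted p = 0.0694 and 0.233) or replicate 1 or 3 of the UV-treated N2 arrays (adjusted p = 0.153 and 0.106). It was also lost with the compared groups alone in the fit (adjusted p = 0.0549) and with eBayes trend and robust options (adjusted p = 0.0551). Genes that mutation of daf-2 raises through DAF-16 (class I) split evenly, 3 of 19 higher and 3 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.78). Of 14 genes that mutation of daf-2 lowers (class II), 6 rose, as also adjusted over the list alone (camera adjusted p = 4.3e-05, and adjusted p = 0.0233 with an estimated correlation). Among them dod-19 was at 1.56 ± 0.10 and dod-24 at 1.15 ± 0.09.

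Of 40 glutathione S-transferase genes 12 rose and 2 fell after UV in N2 (14 and 2 adjusted over the list alone; camera adjusted p = 0.000363, and adjusted p = 0.117 with an estimated correlation). Of 64 UDP-glucuronosyltransferase genes 22 rose and 8 fell (25 and 11 adjusted over the list alone; camera adjusted p = 0.00226, and adjusted p = 0.107 with an estimated correlation). One of them, ugt-13, was at 1.60 ± 0.10. Neuropeptide genes fell, 20 of 53 against 2 that rose (22 and 2 adjusted over the list alone; camera adjusted p = 2.37e-07, and adjusted p = 0.0758 with an estimated correlation). The FMRFamide-like gene flp-3 was at -0.67 ± 0.07. Tissue markers moved beside these groups. Of 25 muscle markers 6 rose and 3 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.00638, and adjusted p = 0.117 with an estimated correlation). Among 19 intestine markers 8 rose and 2 fell (10 and 2 adjusted over the list alone; adjusted p = 0.0107, and adjusted p = 0.325 with an estimated correlation). Among 28 neuron markers 4 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.00397, and adjusted p = 0.0693 with an estimated correlation).

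Over all 17118 genes, 1693 rose and 1392 fell in N2 after UV, 163 and 330 of them by at least 1 on the log2 scale. The values of the UV-treated and mock-treated arrays did not overlap for 35.6% of genes, where chance gives 10%.

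The UV response of xpa-1 answered what the lower dose changed in larvae with the repair gene mutated. The largest rise was that of Y58A7A.5, 11.4-fold, from 6.41 ± 0.23 to 9.92 ± 0.07 (3.51 ± 0.12, adjusted p = 1.96e-12). The transporter gene pgp-8 rose 9.71-fold, ddn-1 rose 8.71-fold, warf-1, a gene of the ARF family of small GTPases, rose 8.33-fold and the log2 difference of pals-6 was 2.81 (SE 0.09 to 0.18 for these genes). The pals family is known to respond to intracellular infection. Falls were smaller, with ptr-16 at 4.22-fold lower (-2.08 ± 0.11) and K01D12.9 at 4.80-fold lower (-2.26 ± 0.22). The cell death activator gene egl-1 rose by 0.70 ± 0.10 (1.63-fold, adjusted p = 1.97e-05), while ced-13 (0.04 ± 0.09) and cep-1 (0.15 ± 0.08) did not pass the test.

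Cuticle collagen genes fell in the mutant too, 79 of 145 against 7 that rose (88 and 9 adjusted over the list alone; camera adjusted p = 6.92e-12, and adjusted p = 0.0427 with an estimated correlation). The risen ones included col-103 (1.87 ± 0.09) and col-149 (1.67 ± 0.08). Of 80 hedgehog-related and patched-related genes 39 fell and 5 rose (42 and 5 adjusted over the list alone; camera adjusted p = 8.9e-09, and adjusted p = 0.0302 with an estimated correlation). One of the fallen genes was grl-16 at -1.75 ± 0.13. Antimicrobial peptide and saposin-like genes rose, 21 of 58 against 3 that fell (25 and 3 adjusted over the list alone; camera adjusted p = 7.57e-05, and adjusted p = 0.0302 with an estimated correlation). Examples were fipr-24 at 1.95 ± 0.16, nlp-27 at 1.86 ± 0.12 and nlp-29 at 1.32 ± 0.09. Of 20 genes of a list of oxidative stress and detoxification linked to the SKN-1 transcription factor, 9 rose (10 adjusted over the list alone; camera adjusted p = 0.00173, and adjusted p = 0.0302 with an estimated correlation). The conjugating enzyme gene ugt-13 was at 1.71 ± 0.10. Neuron markers fell, 11 of 28 against 1 that rose (13 and 1 adjusted over the list alone; camera adjusted p = 0.000487, and adjusted p = 0.0302 with an estimated correlation). These included the synaptic vesicle priming gene unc-13 at -0.73 ± 0.07 and the kinesin gene unc-104 at -0.66 ± 0.08.

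Single DNA damage genes were called in xpa-1, while camera called neither the nucleotide excision repair list nor that of other DNA damage genes. Fry, which does not compare a list with other genes, called both higher (fry adjusted p = 0.00267 and 0.0343). The ATR gene atl-1 rose 2.39-fold (1.26 ± 0.09), csb-1, a gene of transcription-coupled repair, rose by 0.62 ± 0.09 and the ribonucleotide reductase gene rnr-2 rose by 0.64 ± 0.08. Yet 6 of the 36 other DNA damage response genes rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.344). Among other lists, 3 of 14 nucleotide excision repair genes rose, also adjusted over the list alone (camera adjusted p = 0.159), and 3 of 33 DNA replication genes rose and 1 fell, likewise adjusted over the list alone (camera adjusted p = 0.796). Of 29 ribosome biogenesis genes 7 fell, as also adjusted over the list alone, among them the box C/D nucleolar genes nol-56 (-0.65 ± 0.07) and nol-58 (-0.60 ± 0.11). Their camera call (adjusted p = 0.0283) had an adjusted p = 0.614 with an estimated correlation and ended without replicate 1 of the mock-treated xpa-1 arrays (adjusted p = 0.0573) or without replicate 2 or 3 of the UV-treated ones (adjusted p = 0.0763 and 0.061).

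The DAF-16 target gene sod-3 rose by 0.35 ± 0.10 (adjusted p = 0.016), which was lost without replicate 3 of the mock-treated (adjusted p = 0.0818) or replicate 2 of the UV-treated xpa-1 arrays (adjusted p = 0.0561), and egl-27 was at 0.14 ± 0.09 (adjusted p = 0.308). The brightest of 4 daf-16 probe sets showed 0.02 ± 0.09 (adjusted p = 0.897), whereas another showed 0.40 (adjusted p = 0.00627 over all probe sets). Of the 19 class I genes 8 rose and 1 fell, as also adjusted over the list alone (camera adjusted p = 0.0617), with the small heat shock gene sip-1 at 1.52 ± 0.09 and cdr-2 at 1.47 ± 0.11. Camera called that list without replicate 1 or 3 of the mock-treated xpa-1 arrays (adjusted p = 0.0372 and 0.0452) or replicate 1 of the UV-treated ones (adjusted p = 0.0358). Of the 14 class II genes 5 rose and 2 fell, as also adjusted over the list alone (camera adjusted p = 0.0207, and adjusted p = 0.141 with an estimated correlation). In all, 2156 genes rose and 1990 fell, 334 and 242 of them by at least 1 on the log2 scale, and the groups did not overlap for 34.4% of genes (10% by chance).

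Starvation answered how larvae without food differed from mock-treated larvae that had fed, both of the N2 strain. How far the larvae of each group had developed is not given. An effect of lacking food therefore cannot be told apart from a difference in age or developmental progress, here or where UV is set against starvation. The collagen gene sqt-1 fell from 13.07 ± 0.00 to 4.95 ± 0.07 (278-fold lower), dpy-5 was 237-fold lower (-7.89 ± 0.13), the protease inhibitor gene mlt-11, needed for molting, was 142-fold lower (-7.15 ± 0.08) and noah-2, of the apical matrix, was 134-fold lower (-7.06 ± 0.11). The largest difference was that of ZK1025.3, 467-fold lower (-8.87 ± 0.09, adjusted p = 4.62e-22). In the other direction, C18H7.1 rose 75.9-fold (6.25 ± 0.15), the fatty acid and retinol binding protein gene far-3 rose 23.6-fold (4.56 ± 0.17) and the metallothionein gene mtl-1 rose 15.4-fold (3.95 ± 0.14).

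Of 30 molting genes 27 fell in starved larvae and 2 rose, as also adjusted over the list alone (camera adjusted p = 2.52e-17, and adjusted p = 0.00554 with an estimated correlation). Of 145 collagen genes 99 fell and 8 rose (100 and 8 adjusted over the list alone; camera adjusted p = 6.25e-17, and adjusted p = 0.013 with an estimated correlation). Proteasome genes fell in 32 of 33 cases and rose in 1, as adjusted over the list alone (camera adjusted p = 2.86e-18, and adjusted p = 0.00554 with an estimated correlation), with a median of -1.31. DNA replication genes fell in 31 of 33 cases, as adjusted over the list alone (camera adjusted p = 2.81e-12, and adjusted p = 0.0355 with an estimated correlation). For the cell cycle, 36 of 45 cell cycle genes fell while 2 rose (37 and 2 adjusted over the list alone; camera adjusted p = 1.01e-12, and adjusted p = 0.026 with an estimated correlation). The mitotic kinase gene cdk-1 was at -2.17 ± 0.07. Epidermis markers, a list not separate from the collagen genes, fell in 9 of 19 cases and rose in 4, as adjusted over the list alone. Their median was -0.13 and their mean -1.51 (camera adjusted p = 0.0031, and adjusted p = 0.127 with an estimated correlation). The collagen gene rol-6, one of these markers, was at -6.56 ± 0.09. Of 18 genes of the endoplasmic reticulum stress response 13 fell and 2 rose (13 and 3 adjusted over the list alone; camera adjusted p = 4.3e-05, and adjusted p = 0.013 with an estimated correlation). One was the protein disulfide isomerase gene pdi-2 (-2.36 ± 0.08). Among 32 aminoacyl-tRNA synthetase genes 23 fell and 2 rose (24 and 2 adjusted over the list alone; camera adjusted p = 2.31e-06, and adjusted p = 0.028 with an estimated correlation).

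Of 53 neuropeptide genes 46 rose and 1 fell in the starved larvae (47 and 1 adjusted over the list alone; camera adjusted p = 5.37e-18, and adjusted p = 0.00625 with an estimated correlation). Of these, flp-3 was 5.72-fold and nlp-2 5.17-fold higher. Neuron markers rose in 24 of 28 cases (25 adjusted over the list alone; camera adjusted p = 1.11e-06, and adjusted p = 0.00554 with an estimated correlation), such as the proprotein convertase gene egl-3 (1.87 ± 0.08). Muscle markers rose in 16 of 25 cases and fell in 2, as adjusted over the list alone (camera adjusted p = 0.00964, and adjusted p = 0.127 with an estimated correlation), with the myosin gene myo-1 at 1.90 ± 0.08. Intestine markers went both ways, 5 of 19 higher and 9 lower, also adjusted over the list alone (camera adjusted p = 0.281). Of 254 nuclear hormone receptor genes 147 rose and 13 fell (148 and 13 adjusted over the list alone; camera adjusted p = 1.79e-06, and adjusted p = 0.03 with an estimated correlation). The receptor gene nhr-7 was at 3.10 ± 0.08, while the molting regulator nhr-23 fell by 2.91 ± 0.12. Of 26 autophagy and lysosomal lipase genes 15 rose and 3 fell (16 and 3 adjusted over the list alone), led by the lysosomal lipase gene lipl-3 (3.16 ± 0.18); their camera adjusted p = 0.00672 became adjusted p = 0.0831 with an estimated correlation.

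Starved larvae had more daf-16 (1.47 ± 0.09, 2.77-fold, adjusted p = 5.96e-11; 4 of 4 probe sets higher, by 0.92 to 1.84), egl-27 (0.90 ± 0.09, 1.87-fold) and sod-3 (0.91 ± 0.10, 1.88-fold) than mock-treated larvae. The egl-27 value is that of its brightest probe set, and another showed 0.96. Its dim probe sets, with means of 4.05 and 3.78, were not called by limma over all probe sets (-0.07 with adjusted p = 0.661, and 0.11 with adjusted p = 0.376). The insulin receptor gene daf-2, dim on these arrays, was at 0.21 ± 0.09 (adjusted p = 0.0433). That call was lost without replicate 1, 2 or 3 of the mock-treated N2 arrays (adjusted p = 0.0604, 0.0855 and 0.121), without replicate 1 or 3 of the starved arrays (0.133 and 0.195), and with another quantile normalization (0.257), the compared groups alone (0.0794), the replicate number as a block (0.0558) or eBayes trend and robust options (0.0816). Of the 19 class I genes 13 rose and 3 fell, as also adjusted over the list alone (camera adjusted p = 0.0434, and adjusted p = 0.128 with an estimated correlation), with the ferritin gene ftn-1 at 2.40 ± 0.09. That camera call was lost without replicate 2 of the starved arrays (adjusted p = 0.0526) and when dim genes were left out (adjusted p = 0.0703). The 14 class II genes went both ways, 5 higher and 4 lower, also adjusted over the list alone (camera adjusted p = 0.554), and their median (0.10) and mean (-0.35) differed in sign. Altogether 5188 genes rose and 3872 fell, 1545 and 1398 of them by at least 1 on the log2 scale, and the groups did not overlap for 59.3% of genes, where chance gives 10%.

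**Figure D2:**
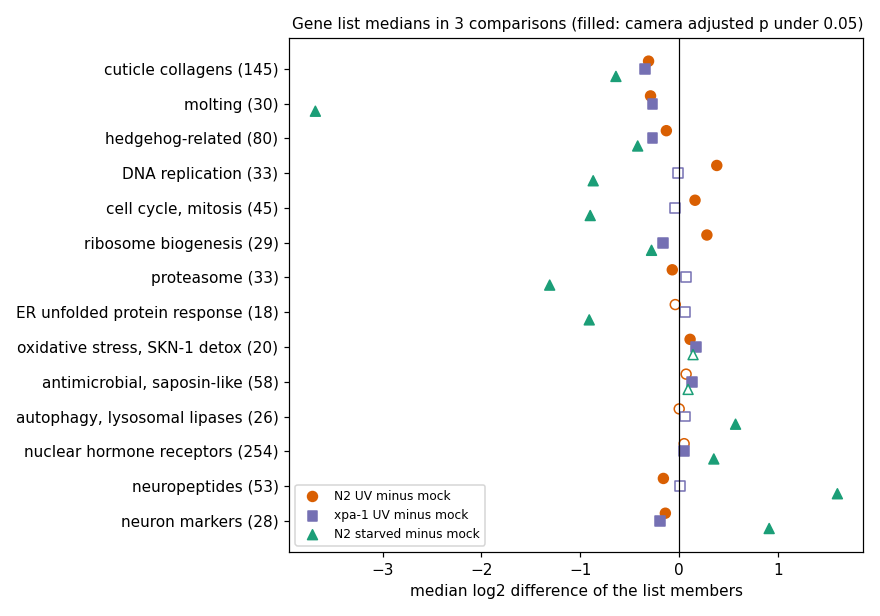
Median log2 difference of the members (horizontal axis) of 14 gene lists (vertical axis, number of measured members in parentheses) in the UV responses of N2 and xpa-1 and the starvation response of N2; filled symbols mark lists with a camera adjusted p under 0.05 at the preset correlation. Starvation gave the largest shifts, with molting genes at -3.68 and neuropeptide genes at 1.60, while DNA replication genes were at 0.38 in N2 after UV and -0.87 in starved N2.

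UV-treated and starved N2 larvae were also set against each other directly. The signals of dbd-2 (321-fold), of the infection response gene irg-4 (198-fold), of noah-2 (163-fold) and of mlt-11 (161-fold) were higher in UV-treated larvae (SE of the log2 differences 0.07 to 0.11), and those of C18H7.1 (58.5-fold) and C23G10.11 (45.5-fold) were lower. Each of the 33 DNA replication genes was higher after UV than in starvation, also adjusted over the list alone (camera adjusted p = 2.5e-16, and adjusted p = 0.0191 with an estimated correlation). So were 32 of 33 proteasome genes, also adjusted over the list alone, with 1 lower (adjusted p = 1.54e-17, and adjusted p = 0.00587 with an estimated correlation). Neuropeptide genes were lower in 46 of 53 cases and higher in 1, as adjusted over the list alone (adjusted p = 1.91e-19, and adjusted p = 0.00587 with an estimated correlation). Neuron markers were lower in 27 of 28 cases and higher in 1, as adjusted over the list alone (camera adjusted p = 1.15e-08, and adjusted p = 0.00516 with an estimated correlation). Epidermis markers were higher in 10 of 19 cases and lower in 1, as adjusted over the list alone. Their median was 0.33 and their mean 1.43 (camera adjusted p = 0.000129, and adjusted p = 0.0605 with an estimated correlation). Intestine markers were higher in 11 of 19 cases and lower in 5, as adjusted over the list alone (camera adjusted p = 0.0428, and adjusted p = 0.369 with an estimated correlation). That camera call ended without replicate 1 of the starved arrays (adjusted p = 0.0597), without dim genes (0.0808) and after another quantile normalization (0.0631). Muscle markers were higher in 5 of 25 cases and lower in 15, as adjusted over the list alone (camera adjusted p = 0.0531). Camera called them without replicate 2 or 3 of the UV-treated N2 arrays (adjusted p = 0.0499 and 0.0421), without replicate 2 of the starved arrays (0.0487) and after another quantile normalization (0.0161). Signals of daf-16 (-0.88 ± 0.09), egl-27 (-0.80 ± 0.09) and sod-3 (-0.60 ± 0.10) were lower after UV than in starvation. The counts were 3936 genes higher and 4916 lower after UV, 1395 and 1529 by at least 1 on the log2 scale, with no overlap of the groups for 57.4% of genes (10% by chance).

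Whether UV and starvation changed shared genes was examined from the called genes and from log2 differences across genes, which are not independent replicates. Of the genes that fell after UV in N2, 842 also fell in starvation, where 314.9 would be found between independent lists, and 747 rose in both against 513.1. Another 643 rose after UV and fell in starvation (382.9 between independent lists) and 359 fell after UV and rose in starvation (421.9). The log2 differences correlated at r = 0.37 (Spearman 0.131), below the 0.5 that simulated unchanged groups gave because both comparisons use the mock-treated N2 arrays, and the covariance was 0.132 against a simulated 0.00539, a difference of 0.126. The simulated unchanged groups shared 0 called genes, but with no gene changed hardly any can be called. That 0 therefore does not gauge how far the shared arrays raise the overlaps of called genes. With the mock-treated arrays split between the comparisons r ranged from 0.311 to 0.38. In xpa-1, whose arrays are not shared with the starvation comparison, 1023 genes fell in both (450.1 between independent lists) and 1097 rose in both (653.4), with r = 0.329 (Spearman 0.183). In opposite directions, 540 rose after UV in xpa-1 and fell in starvation (487.7 between independent lists) and 549 did the reverse (603.1).

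The UV responses of the strains shared 930 risen genes, where independent lists would share 213.2, and 899 fallen ones (161.8), while 71 rose in N2 and fell in xpa-1 (196.8) and 42 did the reverse (175.3). Across genes r was 0.668 (Spearman 0.454). Of the 899 genes that fell after UV in both strains, 70.6% were lower in starved N2 and 19.5% higher, against 22.6% and 30.3% of all genes. Of the 930 that rose in both, 53.9% were higher and 30.4% lower in starved N2.

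The strains differed before UV. Besides xpa-1 itself, the lysozyme gene ilys-5 (4.93-fold), the esterase gene cest-5.2 (4.60-fold) and the dehydrogenase gene dhs-25 (4.19-fold) were lower in mock-treated xpa-1 than in mock-treated N2 (SE of the log2 differences 0.11 to 0.18). Higher in the mutant were srw-85, a chemoreceptor gene (14.2-fold, 3.82 ± 0.12), mks-6, a gene of the ciliary transition zone (9.77-fold, 3.29 ± 0.10), the collagen gene col-39 (9.70-fold, 3.28 ± 0.13) and the lectin gene clec-52 (7.95-fold, 2.99 ± 0.10). In the reference gene table (assembly WBcel235) mks-6 is the direct neighbour of xpa-1, and it stood at 8.36 ± 0.13 in mock-treated xpa-1 against 5.07 ± 0.08 in mock-treated N2.

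Collagen genes were higher in the mock-treated mutant, 40 of 145 against 1 lower (60 and 2 adjusted over the list alone; camera adjusted p = 1.04e-17, and adjusted p = 0.0297 with an estimated correlation). The higher ones included col-159 (2.45 ± 0.14), col-91 (1.91 ± 0.16) and col-12 (1.90 ± 0.12). Of 18 genes of the endoplasmic reticulum stress response 3 were lower (6 adjusted over the list alone; camera adjusted p = 6.42e-07, and adjusted p = 0.0139 with an estimated correlation). Among them were hsp-4, the worm BiP chaperone gene (-0.73 ± 0.10), and ckb-2, a choline kinase gene (-0.95 ± 0.09). Ribosome biogenesis genes had 2 of 29 higher (7 adjusted over the list alone; camera adjusted p = 2.01e-05, and adjusted p = 0.465 with an estimated correlation). In mock-treated xpa-1 larvae sod-3 was 0.50 ± 0.10 higher (adjusted p = 0.00421) and mtl-1 1.31 ± 0.14 higher, while daf-16 (0.14 ± 0.09), egl-27 (-0.08 ± 0.09) and daf-2 (-0.29 ± 0.09, adjusted p = 0.0565) did not pass the test. The test called daf-2 with centred arrays (adjusted p = 0.0186), another quantile normalization (0.0295), array weights (0.00762) or without dim genes (0.0442). Without UV, 646 genes were higher and 329 lower in the mutant, 100 and 17 by at least 1 on the log2 scale, and the groups did not overlap for 22.6% of genes (10% by chance). The split depended on the scale of the arrays, with 66.3% of calls higher as deposited, 46.5% with arrays centred on their medians (532 higher and 613 lower) and 57.4% after another quantile normalization (617 and 458); array weights gave 679 lower, and without replicate 2 or 3 of the mock-treated N2 arrays 195 or 199 genes were lower.

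The UV responses of the strains were compared by the interaction, the response of xpa-1 at the lower dose minus that of N2 at the higher dose. In the difference ddn-1 was 13.4-fold higher, Y58A7A.5 was 10.6-fold higher and the cytochrome P450 gene cyp-14A5 was 6.94-fold higher. The gene eol-1, which encodes a decapping exonuclease relative, was 7.57-fold higher, and pals-6 was higher by 3.62 ± 0.26 on the log2 scale. The signal of pals-6 went from 5.56 ± 0.40 to 4.75 ± 0.21 with UV in N2 and from 4.94 ± 0.23 to 7.75 ± 0.15 in xpa-1. Lower in the difference were Y48E1B.8 (5.68-fold), the peroxisomal acyl-CoA oxidase gene acox-1.2 (5.17-fold) and nspe-1 (3.70-fold). The cell death activator egl-1 was 1.74-fold higher (adjusted p = 0.000926), and daf-16 was 1.48-fold lower (adjusted p = 0.00959) on its brightest probe set. That daf-16 call was lost with the mean of its 4 probe sets (adjusted p = 0.0516), and the other three, tested alone, were not called (-0.20, -0.12 and -0.42).

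Of 29 ribosome biogenesis genes 16 were lower in the difference by limma (20 adjusted over the list alone; camera adjusted p = 2.53e-13, and adjusted p = 0.0822 with an estimated correlation). They included nol-56 (1.90-fold) and the fibrillarin gene fib-1 (1.65-fold). DNA replication genes were lower in 13 of 33 cases (20 adjusted over the list alone; camera adjusted p = 5.11e-10, and adjusted p = 0.124 with an estimated correlation). The helicase genes mcm-2 (1.70-fold) and mcm-6 (1.66-fold) were examples. Muscle markers were lower in 7 of 25 cases (8, with 1 higher, adjusted over the list alone; camera adjusted p = 0.000902, and adjusted p = 0.124 with an estimated correlation), including the muscle genes unc-89 (2.17-fold) and myo-2 (2.02-fold). Intestine markers were lower in 4 of 19 cases (6 adjusted over the list alone; adjusted p = 0.000884, and adjusted p = 0.232 with an estimated correlation), including the peptide transporter gene pept-1 (1.94-fold). Antimicrobial peptide and saposin-like genes were higher in 13 of 58 cases and lower in 1 (16 and 1 adjusted over the list alone; camera adjusted p = 0.000458, and adjusted p = 0.0822 with an estimated correlation). Of these, cnc-4 was 2.66-fold and nlp-29 1.97-fold higher. Neuropeptide genes were higher in 6 of 53 cases (7 adjusted over the list alone; adjusted p = 0.000109, and adjusted p = 0.232 with an estimated correlation), with flp-3 1.94-fold higher. Class I genes were higher in 3 of 19 cases, as adjusted over the list alone (adjusted p = 0.00471, and adjusted p = 0.124 with an estimated correlation), sip-1 2.56-fold and cdr-2 2.58-fold.

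The interaction called 799 genes higher and 665 lower, 166 and 41 by at least 1 on the log2 scale. Of the 799, 524 rose in xpa-1 after UV and 300 fell in N2. Of the 665, 378 fell in xpa-1 and 330 rose in N2. Without replicate 2 of the mock-treated N2 arrays the lower count was 442. Of the 13 lists called by camera in the interaction, 0 kept the call with an estimated correlation (10 lists had an unadjusted p under 0.05 there, and fry called 12 of the 13), and no UV dose above 0 was given to both strains.

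**Figure D3:**
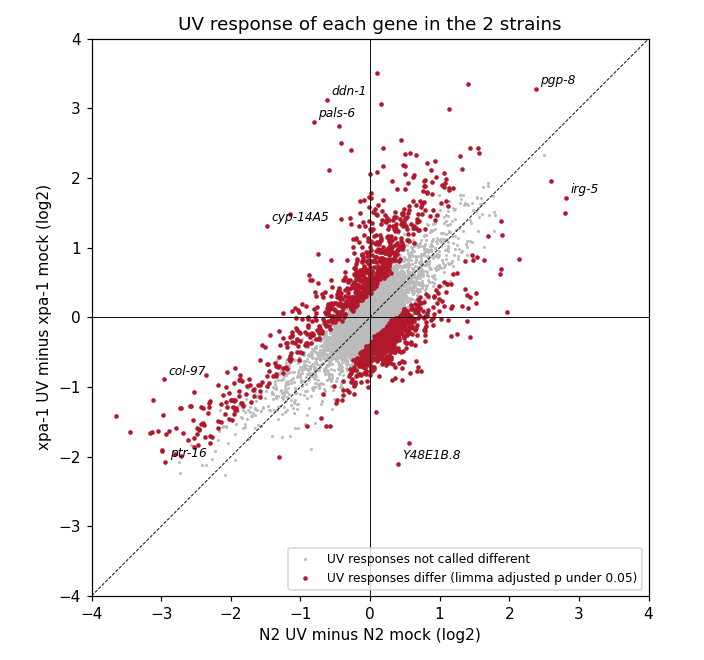
UV response of each of 17118 genes in N2 (horizontal axis, log2) and xpa-1 (vertical axis, log2), as points; red points are the 1464 genes whose UV responses differ at a limma adjusted p under 0.05, and the dashed line marks equal responses. The correlation across genes was 0.668, and pals-6 and ddn-1 lie far above the line.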

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

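The pals family and the test of the dose on it were chosen after the result was seen; the test of shared probe sets was fixed before its result was seen, and the interaction itself and the probe sets without a single gene were planned.

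The results below stood out because the UV response differed between the strains by the interaction test, in which the strain and the dose change together. It called 799 genes higher and 665 lower in xpa-1, 166 and 41 of them by at least 1 on the log2 scale. In 2 of the 100 splits drawn, the real one with 1464 included, as many genes were called, and the highest other called 1902. These splits do not settle whether chance gives such a count, because the strains differ without UV. The 7 other splits that kept the UV-treated arrays of each strain together while mixing the mock-treated ones called 902 to 1902 genes, which points to that structure of the samples. The 92 that mixed the UV-treated arrays called at most 65, with the strain difference in their spread. No drawn split other than the real one kept the strains apart in both treatments.

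Among single genes the log2 difference between the responses was 3.75 for ddn-1, 3.62 for pals-6, 3.40 for Y58A7A.5, 3.19 for B0507.8, 2.92 for eol-1, 2.91 for warf-1, 2.79 for cyp-14A5 and 2.70 for ugt-29. At the other end Y48E1B.8 was at -2.51, acox-1.2 at -2.37, nspe-1 at -1.89 and piit-1 at -1.72. The collagen genes col-97 (2.07) and col-48 (1.46) were higher in the difference, as were cnc-4 (1.41), cdr-2 (1.37), sip-1 (1.35), nlp-29 (0.98), flp-3 (0.96), egl-1 (0.80) and atl-1 (0.56). The muscle genes unc-89 (-1.12), unc-22 (-1.07) and myo-2 (-1.02) and the intestinal gene pept-1 (-0.96) were lower, together with nol-56 (-0.93), fib-1 (-0.72), mcm-2 (-0.76), mcm-6 (-0.73) and daf-16 (-0.56).

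Gene lists that differed between the strains' UV responses had median log2 differences of -0.47 for ribosome biogenesis, -0.38 for DNA replication, -0.21 for the cell cycle, -0.18 for translation factors (a name pattern that also took in the intermediate filament genes ifb-1 and ifb-2), -0.14 for intestine markers, -0.12 for fat synthesis, -0.10 for other DNA damage genes and -0.09 for muscle markers. Medians above 0 were 0.15 for the proteasome, 0.15 for neuropeptides, 0.11 for antimicrobial peptides and saposin-like proteins, 0.08 for class I genes and 0.03 for collagens. Each of these calls ended with an estimated correlation. Of 145 collagen genes 12 were higher and 2 lower (13 and 2 adjusted over the list alone; camera adjusted p = 0.0253, and adjusted p = 0.511 with an estimated correlation). The collagen call also ended without replicate 3 of the mock-treated N2 arrays (adjusted p = 0.111), replicate 2 of the mock-treated xpa-1 arrays (adjusted p = 0.131) or replicate 1 of the UV-treated xpa-1 arrays (adjusted p = 0.098). The call of the other DNA damage genes (adjusted p = 0.0391) ended without replicate 2 of the mock-treated N2 arrays (adjusted p = 0.104), replicate 3 of the UV-treated N2 arrays (0.0771), replicate 1 or 2 of the mock-treated xpa-1 arrays (0.0692 and 0.0792) or replicate 1 of the UV-treated xpa-1 arrays (0.0681). The fat synthesis call (adjusted p = 0.0474) ended without dim genes (adjusted p = 0.0699) and in 8 fits that left out 1 array. These lacked replicate 2 or 3 of the mock-treated N2 arrays (0.0542 and 0.0665), replicate 2 or 3 of the UV-treated N2 arrays (0.0774 and 0.0771), replicate 1 or 2 of the mock-treated xpa-1 arrays (0.0949 and 0.0536) or replicate 2 or 3 of the UV-treated xpa-1 arrays (0.107 and 0.0543).

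Of 23 measured pals genes 12 had a higher UV response in xpa-1 than in N2 (camera adjusted p = 2.98e-12 over 233 name families, and adjusted p = 0.191 with an estimated correlation), and over the 23 the median response was 0.50 in xpa-1 and -0.04 in N2. Their median difference between the mock-treated strains was -0.03. Of the members on probe sets without an x or s suffix 54.5% (12 of 22) were called. As 22 of the 23 lack the suffix, nearly all called members had to be among them. The share therefore does not decide whether probe sets that bind several members are the source. Probe sequences were not examined. The dose cannot be told apart from the strain, because 0 doses above zero were given to both. The pattern may reflect the strain, the lower dose or something else that differed between the groups of larvae. None of these was tested.

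Signal also appeared in data outside the gene-level comparisons, in the 1782 probe sets with several genes or none, tested together with the others. UV changed 171 of them in N2 and 275 in xpa-1, starvation changed 598, and 88 differed between the mock-treated strains. These are 9.6%, 15.4%, 33.6% and 4.9%, against 17.7%, 24.3%, 53.7% and 5.3% of probe sets with 1 gene.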

How the results depend on the processing

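The alternative without x or s probe sets was chosen after seeing the data, and the others were planned. Over 16702 values of named genes under the alternatives, 15863 kept their side of the threshold, 831 lost the call and 8 gained it; among the 15863, 28 that were called under neither setting differed in sign. Of 3384 values of lists, 3166 kept their side, 112 uncalled ones with another sign among them, 115 lost the call and 102 gained it. In 1 case an uncalled direction became a call the other way, the glutathione S-transferase list between UV and starvation in N2, which fry put higher after UV (adjusted p = 0.000521) where camera had it lower without a call (adjusted p = 0.965); fry does not compare a list with other genes.

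A required difference of 0.5 by limma's treat lowered counts by its construction, to 229 higher and 384 lower for UV in N2, 446 and 307 for UV in xpa-1, 2299 and 1916 for starvation, 90 and 17 between mock-treated strains, 107 and 30 for the interaction (105 higher by at least 1) and 2004 and 2216 for UV against starvation. Without x or s probe sets, where fewer genes are tested, UV raised 1063 genes in N2, UV raised 1435 and lowered 1299 in xpa-1, starvation lowered 2420 (889 by at least 1), 11 genes were lower by at least 1 between mock-treated strains, 358 were lower in the interaction and 2404 were higher in UV than in starvation (846 by at least 1). Between mock-treated strains 613 genes were lower with centred arrays and 679 with array weights, and the cause was not tested. Leaving out 1 array gave 195 to 300 genes lower between mock-treated strains and 442 to 634 lower in the interaction, with fewer samples in the fit. The other counts of genes stayed within 1.5 times their value under the alternatives run.

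The correlation of the UV responses was 0.688 without dim genes, 0.715 over genes called in either, and 0.636 to 0.696 leaving out 1 array. For N2 UV and starvation it was 0.336, 0.38, 0.369, 0.311, 0.358 and 0.352 with mock-treated arrays split, and 0.36 to 0.386 leaving out 1 array. For xpa-1 UV and starvation it was 0.336 without dim genes, 0.338 over called genes, 0.34 after quantile normalization and 0.312 to 0.342 leaving out 1 array. The cause was not tested.

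Replicate numbers showed no clear pairing of the samples. Of 30 pairs of arrays with 1 number, 10 had a correlation of deviations over 0.1, and 7 of 15 arrays matched their own number best. The median was 0.031 for these pairs, against -0.0325 for other pairs, so a weak batch by replicate number is not excluded. With the replicate number as a block the counts were 1702 higher and 1418 lower for UV in N2, 2175 and 2033 for UV in xpa-1, 5235 and 3911 for starvation, 663 and 342 between mock-treated strains, 836 and 663 for the interaction and 3948 and 4951 for UV against starvation.

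Each comparison of 3 against 3 arrays has 10 splits, too few for a share under 0.05; the real split was 1 of 10, with 3085 genes for UV in N2 (highest other 0), 4146 for UV in xpa-1 (3), 9060 for starvation (0), 975 between mock-treated strains (0) and 8852 for UV against starvation (0). A gene's probe sets were called in opposite directions for 1, 7, 25 and 29 of 2981 genes (UV in N2, UV in xpa-1, starvation, UV against starvation). Among those genes with any probe set called, all were called the same way for 368 of 820, 449 of 1207, 1483 of 2200 and 1484 of 2166. Between mock-treated strains this held for 45 of 244 genes and in the interaction for 109 of 432. Many calls were thus not repeated by the gene's other probe sets. Without detection calls, how far dim genes lie above background stays unknown.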

Other observations

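The tests of the array scale and of the segment around xpa-1 were fixed before their results were seen, and the other tests of explanations given here were chosen after the patterns were seen.

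The fatty acid elongase gene elo-4 fell by 1.15 ± 0.10 after UV in N2, by 0.62 ± 0.10 after UV in xpa-1 and by 4.70 ± 0.10 in starvation, where the desaturase gene fat-5 rose by 2.74 ± 0.12. After UV in N2, 10 of 21 fat synthesis genes rose and 3 fell (12 and 3 adjusted over the list alone; camera adjusted p = 0.00185, and adjusted p = 0.0811 with an estimated correlation). Camera did not call that list after UV in xpa-1 (5 higher and 3 lower, also adjusted over the list alone, adjusted p = 0.62) or in starvation (12 higher and 8 lower, also adjusted over the list alone, adjusted p = 0.415). In starved larvae 19 of 31 beta-oxidation genes fell and 5 rose, as also adjusted over the list alone (camera adjusted p = 0.000636, and adjusted p = 0.253 with an estimated correlation), with the acyl-CoA dehydrogenase gene acdh-1 at -3.18 ± 0.10 and acox-1.2 at -3.82 ± 0.15.

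In starvation 12 of 24 insulin-like peptide genes rose and 1 fell, as also adjusted over the list alone (camera adjusted p = 0.0211, and adjusted p = 0.139 with an estimated correlation), with ins-17 at 1.83 ± 0.08, ins-18 at 1.58 ± 0.09 and ins-33 at -2.23 ± 0.12. Innate defence lists were not called by camera there and went both ways. Lysozyme genes were higher in 3 and lower in 8 of 16 cases, as adjusted over the list alone (adjusted p = 0.0747, or 0.0364 without dim genes). Antimicrobial peptide and saposin-like genes were higher in 19 and lower in 16 of 58 cases, as adjusted over the list alone (adjusted p = 0.675, median 0.09 and mean -0.18). C-type lectin genes were higher in 36 and lower in 34 of 220 cases, or 31 and 32 adjusted over the list alone (adjusted p = 0.602, median 0.04 and mean -0.05). Among single genes, the lysozyme gene ilys-5 was 58.8-fold lower, the saposin-like gene spp-13 was 45.3-fold lower and the lectin gene clec-180 was 52.5-fold lower, while clec-47 was 20.2-fold higher and fipr-2 was 14.8-fold higher (SE of the log2 differences 0.08 to 0.18). After UV in xpa-1, ins-37 rose by 1.18 ± 0.09 and ins-7 by 1.01 ± 0.15, while ins-22 was at -1.07 ± 0.10 and ins-6 at -0.95 ± 0.11.

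Many genes changed by UV were also changed by starvation. The shared mock-treated N2 arrays are argued against as the whole source, since genes lower in both xpa-1 UV and starvation, comparisons with no array in common, were 2.27 times as many as between independent lists. A shift of N2 towards the starved state as the whole UV response is argued against as well, since 38.7% of the genes called in both (1002 of 2591) went opposite ways. Medians after UV in N2 and in starvation had opposite signs for DNA replication (0.38 and -0.87), ribosome biogenesis (0.28 and -0.28) and cell cycle genes (0.16 and -0.90, 12 of 45 higher after UV, 13 adjusted over the list alone). These lists thus did not move after UV as they did in starvation, though their camera calls after UV ended with an estimated correlation (adjusted p = 0.0693, 0.0982 and 0.2). Transcript levels at 1 time do not show whether growth was slowed. A slowing of growth may lie behind the genes lower in both, which made up 60.5% of those that fell after UV in N2, but growth was not measured and there is no time course, so this stays open.

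Collagen genes were higher in the mock-treated mutant than in mock-treated N2. Of the 40 called collagen genes 2.5% (1 gene) lay among the 100 measured genes on either side of xpa-1. For the others, being carried in that segment is argued against. Among those neighbours 9.5% of genes of all kinds were called, against 5.7% elsewhere. A longer segment, or an effect of the segment on genes elsewhere, would not show in this count and stays open. With arrays centred on their medians 87.5% of the 40 (35 genes) stayed higher. Centring moved the median difference over all genes only from 0.006 to -0.041, too little to end most calls, so that share decides little. The collagen list's median was 0.22, which argues against a shift between whole arrays as its source. Centring leaves the spread and the brightest signals of the arrays as they were. The list's camera call held after another quantile normalization. A different phase of the molting cycle in the cultures may contribute and stays open, as 13.3% of 30 molting genes were called, all 4 of them higher, while 4 were higher and 9 lower adjusted over the list alone (median -0.12; camera adjusted p = 0.144, or 0.0394 without replicate 2 of the mock-treated N2 arrays), and the larvae were sampled at 1 time. The strain itself stays open as a biological explanation.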
